A study of Danio rerio with 7 samples.

How the data were processed

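The series holds 7 single-cell RNA-seq libraries of zebrafish larvae at 5 days post fertilization (dpf). Cells positive for green fluorescent protein (GFP) were sorted from transgenic larvae in which the Et20 line gives GFP and the myo6b promoter drives a red nuclear reporter (H2B-mScarlet-I), per the labels. The labels name 1 untreated library (homeostasis) and 1 library each at 0 min, 30 min, 1 h, 3 h, 5 h and 10 h after neomycin, with no replicate of any group. Libraries were made with droplet chemistry version 2 of 10x Genomics, per the labels' protocols.

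The authors deposited, for each library, a matrix of UMI counts (counts of unique molecular identifiers) per gene and cell barcode that had already passed a cell caller. The submitters' processing notes name Cell Ranger 2.1.1 and the genome builds GRCz10 and danRer10, which are names of the same assembly. The annotation release and the settings of the cell caller were not given in the sources used here. The deposited count matrices list 35117 genes in 6 libraries and 32266 in the 3 h library, and the homeostasis and 3 h matrices are in an older file format than the other 5. The lowest UMI count of any barcode was 1022 in the homeostasis library, 1684 at 3 h and 500 in the other 5, so the callers kept cells down to different depths. Genes were matched by Ensembl ID, and the 31765 IDs shared by all libraries were used. They held at least 99.0336% of the UMIs of each library. Gene names are those paired with the IDs in the deposited files. No genome of the build was used here, so no coordinates are given.

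Cells with at least 500 UMIs, at least 250 genes and at most 20% mitochondrial UMIs were kept. Doublets were removed per library by the highest scrublet scores, at a rate of 0.8% per 1000 barcodes, which took out between 88 barcodes at 3 h and 1379 at 1 h. The filters left 4884 cells at homeostasis, 5356 at 0 min, 5610 at 30 min, 10634 at 1 h, 3224 at 3 h, 3503 at 5 h and 3221 at 10 h. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes, 40 principal components and 15 neighbours entered Leiden clustering at resolution 1.0, with no batch integration and a fixed seed.

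With these settings, which were fixed before the data were examined, clusters followed haemoglobin and cell cycle genes. Both of the following steps were therefore added after the data had been seen. First, 59 barcodes with at least 5% erythroid UMIs were set apart, and 587 genes were left out of the clustering of the other 36373 cells, namely erythroid, S and G2/M genes and genes correlated with them at r above 0.15. Second, clusters with conflicting markers were split once, which turned 26 clusters into 30. Clusters were named only from markers fixed beforehand and needed at least 3 detected markers. The mean log2 fold of the class markers against other cells (marker score) also had to reach a limit. That limit was lowest for central and polar support cells, where support markers among the leading genes could replace it. Cluster 12, named polar-like, had a polar marker score of 0.252 and a support marker score of −0.254. Where the 10 leading genes held more markers of another class, clusters too small to split stayed unnamed. Parts of a split cluster then took that other class if at least 3 of these genes were its markers, and else stayed unnamed. The classes are therefore rebuilt names (support-cell-like, with central-like, polar-like and mantle-like subsets; hair-cell-like; progenitor-like) and not the authors' annotation.

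For each class and library, UMIs were summed over cells and given as CPM, UMIs per 1000000 UMIs of that sum. Ratios are ratios of CPM. The size rule, fixed beforehand, asks for at least 50 UMIs in both sums together, a ratio of at least 2-fold and an interval bound nearest to 1 beyond 1.5-fold. Intervals are exact 95% intervals (conditional binomial for ratios, Poisson for CPM, Clopper-Pearson for shares). They cover counting error only, since every group is 1 library, and no p-value was computed. Medians over genes have order-statistic intervals of about 95%, which show the spread between genes and take the genes as independent. Where a gene had 0 UMIs on one side, the ratio is a lower bound against a floor of 3 UMIs over the class. A set of 492 genes at least 5 times higher in hair-cell-like than in support-cell-like cells at homeostasis was kept out of the named genes.

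For each time, the 8 higher and 8 lower genes whose bound lay farthest from 1 were named, without mitochondrial and ribosomal protein genes, markers of classes outside the neuromast and clone-style names. From each of 22 gene lists, the 4 members with the largest ratio at any time were named, and 9 genes of interest (foxg1a, sox4a, atoh1a, dld, her4.1, prdx1, fgf3, fgf10a and isl1) were always given. After the data had been seen, the rule was widened to 16 genes per direction with no single cell above 10% of the UMIs, and genes from this set are used beside the others. For the time course and the hair-cell-like cells, 5 genes were taken per library and direction.

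The 22 lists cover immediate early and AP-1 genes, heat shock, endoplasmic reticulum stress, oxidative stress, inflammation, Notch, hair cell progenitor genes, neuromast transcription factors, FGF, Wnt, TGF-beta and BMP, Hippo-YAP, retinoic acid, p53 and apoptosis, S phase, G2 and M phase, G1 cyclins, ribosome biogenesis, glycolysis, epithelial structure, hair cell synapse and mechanotransduction, and mitochondrial genes. A list is given as the median log2 ratio of members with at least 20 UMIs in both sums, with 0.5 UMI added to each sum, and as its percentile among 10000 random lists of equal size matched on expression, as a description of these libraries.

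Cycling was scored in cells thinned to 1000 UMIs, as the share with at least 2 UMIs of the G2 and M list. Alternatives covered the cell filter, doublets, clustering, scaling (edgeR 4.0.16 TMM factors and DESeq2 1.42.0 median-of-ratios factors on the class sums of the deposited counts), gene matching, gene minimum, cell weighting and the reference library. On simulated counts with 200 genes altered by known folds, the size rule recovered 45 of 50 genes at 3-fold and none of 50 at 1.5-fold for 0 min against homeostasis (8105 genes), with 0 of 7905 unaltered genes meeting the rule. The simulation drew both sides as Poisson counts from 1 profile without variation between libraries, so it checks the rule for counting error alone. In 5 random splits of the homeostasis support-cell-like cells into equal parts, between 1 and 4 genes met the rule. The same splits gave 9 to 14 genes at 3 h, 3 to 10 at 5 h and at most 7 in each other library.

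The analysis used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0 and matplotlib 3.10.9, and R 4.3.3.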

Results

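Neuromasts are the sensory organs of the zebrafish lateral line, in which mechanosensory hair cells sit among central, polar and outer mantle support cells. Neomycin is an aminoglycoside antibiotic that kills hair cells, and the series is about their regeneration, so the question was which genes the support cells expressed at set times after the treatment. GFP-positive cells were profiled without treatment (homeostasis) and at 0 min, 30 min, 1 h, 3 h, 5 h and 10 h after neomycin, with 1 library per group. The files held 5099, 6817, 6727, 13257, 3314, 4004 and 3450 barcodes in that order, with 12448784, 11529778, 10779332, 23437036, 12187524, 8834405 and 8491185 UMIs. Median depth per barcode was 2018, 1164, 1137, 1370, 2935, 1545 and 1612 UMIs. As no group had a replicate, no difference was tested. All intervals below are 95% intervals that cover counting error only, except those of medians over genes, which show the spread between genes.

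Support-cell-like cells made up 62.3% of cells at homeostasis, 53.6% at 0 min, 52.3% at 30 min, 54.7% at 1 h, 37.0% at 3 h, 45.8% at 5 h and 77.9% at 10 h. The other large group, 5 clusters that met no class, had 23.2, 35.6, 34.5, 33.9, 43.7, 27.4 and 9.97% of cells. Their leading genes were nkx2.7, sostdc1a, sostdc1b, dlx4a, cxcr4a and hoxb1b, and they are called unnamed cells here and used as a comparison class from the same libraries. Which of the 5 clusters held most of them differed too: 2 and 3 at homeostasis (412 and 404 of 1134 cells), 11 at 0 min (1082 of 1905), 3 and 2 at 30 min (587 and 573 of 1935) and 1 h (1259 and 1143 of 3603), 2 at 3 h (1100 of 1410), and 3 at 5 h (479 of 961) and 10 h (147 of 321). A ratio in unnamed cells therefore also reflects which clusters they came from. Smaller classes were leukocytes, mesenchyme, epidermis, ionocytes, endothelium and digestive cells. Cells outside the neuromast classes, the unnamed ones included, came to 30.2, 43.4, 43.5, 42.7, 56.8, 44.99 and 20.4%. Shares depend on the GFP gate and on the lowest depth kept, which differed between the libraries.

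Hair-cell-like cells, a single cluster led by s100t, anxa5a, pvalb8 and otofb, were 5.07% (4.36 to 5.87) of neuromast cells at homeostasis. Their share was 2.84% (2.28 to 3.49) at 0 min, 3.09% (2.52 to 3.76) at 30 min, 0.755% (0.554 to 1.01) at 1 h, 6.10% (4.90 to 7.48) at 3 h, 1.35% (0.883 to 1.97) at 5 h and 0.234% (0.0859 to 0.508) at 10 h. Among cells with at least 1700 UMIs, a limit near the lowest depth at 3 h, the shares were 6.96, 6.86, 6.96, 1.71, 6.13, 2.46 and 0.503%, so the gap of 0 min and 30 min to homeostasis was not seen above this common minimum. The result also depends on where the class ends, since cluster 17, counted as progenitor-like below, has 2 hair cell markers among its 10 leading genes. Together with it the shares were 9.45, 5.08, 7.199, 3.97, 13.8, 3.27 and 1.44%, so that 1 h was at 3.97 against 9.45% and not at 0.755 against 5.07%. Progenitor-like cells, 2 clusters led by dld, dlb and sox4a or by rbm24a, tuba1a and insm1b, were 5.63% (4.88 to 6.46) at homeostasis, 2.38% (1.86 to 2.98) at 0 min, 4.23% at 30 min, 3.66% at 1 h, 8.32% (6.92 to 9.90) at 3 h, 15.4% (13.8 to 17.05) at 5 h and 1.95% (1.45 to 2.56) at 10 h. With at least 1700 UMIs the shares were 6.79% (5.78 to 7.91) at homeostasis, 8.36% (6.96 to 9.95) at 3 h and 8.05% (6.48 to 9.86) at 5 h, with overlapping intervals, and 71.0% of the cells in the first of these clusters came from the 5 h library.

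**Figure D1:**
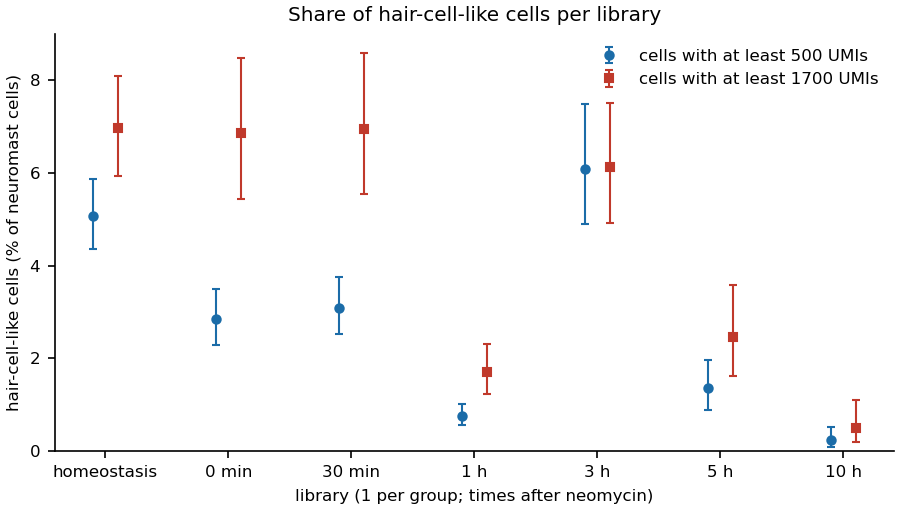
Hair-cell-like cells as a percentage of neuromast cells (y axis) in each of the 7 libraries (x axis), over all kept cells and over cells with at least 1700 UMIs, with exact 95% binomial intervals. Over all kept cells the share ran from 0.234% at 10 h to 6.10% at 3 h, and above 1700 UMIs from 0.503% to 6.96%.

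Different clusters held most of the support-cell-like class in different libraries, so the values below compare cluster 8 (central-like), 12 (polar-like) and 5 (mantle-like) at homeostasis with others. At 0 min these were 7 and 18 (central-like, mantle-like), at 30 min and 1 h 1, 4 and 5 (polar-like, central-like, mantle-like), at 3 h 13 (central-like), at 5 h the parts of 10 (central-like), 12 and 5, and at 10 h 6 (central-like). Clusters 7, 18, 13 and 6 took 97.9, 97.5, 97.9 and 91.3% of their cells from 1 library, 2 central-like parts of 10 took 92.6 and 79.7% from 5 h, and cluster 8 took 82.1% from homeostasis. Each of these may be that library and not a type. Of the genes named below, isl1, sox3, fgf3, fgf10a, her4.1, her4.2, gata2a, prox1a and fat1b are also support cell markers used in naming. So are atoh1a, dld, insm1a, insm1b and hes6, as hair cell progenitor markers, and cldni, as an epidermis marker. The hair cell progenitor list shares such markers, so its medians depend on which cells were set apart as progenitor-like. The genes cst14b.2, il11b, ins, rn7sk, gata2b, her4.1, her4.2, fndc7a, rrm2, mdkb and dld lead clusters that make up the class. Median depth of the class was 1966.5, 1240, 1205, 1375.5, 2946, 2056 and 1561 UMIs, from homeostasis to 10 h.

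At 0 min, support-cell-like cells held far more RNA of immediate early genes, the first genes induced by many stimuli, than at homeostasis. The AP-1 subunit gene fosab was 111-fold higher (100 to 124), at 6321 against 56.9 CPM, fosl1a 763-fold (327 to 2353; 2671 against 5 UMIs) and fosb 1015-fold (281 to 8392; 1421 against 2 UMIs). The zinc finger genes egr2a and egr2b were 428-fold (167 to 1572) and 613-fold (110 to 24270; 429 against 1 UMIs) higher, and egr3 at least 72.9-fold. Also higher were dusp2, a MAP kinase phosphatase, 399-fold (155 to 1470), jdp2b, an AP-1 repressor, 127-fold (92.8 to 178), and socs3a, a feedback inhibitor of cytokine signalling, 208-fold (88.9 to 644). Of 30 measured immediate early genes, 25 met the size rule as higher and 0 as lower. Their median was 5.198 log2 units, or 5.45 relative to the median of all genes with at least 20 UMIs of −0.26, and it was 3.64 in unnamed cells and 2.70 in leukocytes.

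Other genes that were higher at 0 min were the antiproliferative gene btg2 at 95.8-fold (82.8 to 111), cebpb at 90.1-fold and chac1 at 20.8-fold (18.7 to 23.1; unnamed 17.8-fold). Higher by list were also cdkn1cb, a cell cycle inhibitor, at 30.9-fold (18.4 to 55.8), the progenitor genes insm1b at 25.01-fold (11.1 to 69.7) and insm1a at 8.44-fold, the Notch effector hes2.2 at 13.0-fold, mycb at 8.11-fold, gadd45ab at 4.88-fold and ltbp1 at 4.198-fold. Among lower genes, sox3, a SoxB1 factor of sensory progenitors, was 21.7-fold lower (17.8 to 26.7; unnamed 1.78-fold), wnt11 21.5-fold (12.7 to 39.6), ypel3 10.25-fold (6.89 to 15.9) and the chemokine gene ccl20a.3 13.4-fold (8.25 to 23.3). The enzyme gene gsta.2, a glutathione transferase, was 83.0-fold lower (28.2 to 405; 3 against 356 UMIs), cyp2aa3, a cytochrome P450, at least 17.7-fold, cyth4b 77.7-fold (13.7 to 3095; 1 against 111 UMIs) and cox7a1 29.4-fold (7.89 to 247). In unnamed cells gsta.2 was also 89.1-fold lower and cyth4b 30.2-fold. Of the other lists, inflammation had a median of 1.497 (12 higher and 1 lower of 25; unnamed 1.35), and hair cell progenitor genes 1.16 (5 and 1 of 15; unnamed −0.80). The ribosome biogenesis median was lower at −0.68 (0 and 10 of 70; unnamed −0.16). Mitochondrial genes at −0.50 (2 and 5 of 35; unnamed −0.29), neuromast transcription factors at −0.49 (1 and 12 of 32; unnamed −0.29) and heat shock at −0.48 (0 and 4 of 21; unnamed −0.44) lay at percentiles 7.725, 11.44 and 17.24 of matched random lists, and so within their range. In all, 795 genes met the size rule as higher and 1085 as lower, of 8105 with enough UMIs. Higher genes were 42.3% of those that met the rule, against 63.4% with TMM and 57.9% with median-of-ratios scaling. Of the higher genes measured in unnamed cells, 49.6% met the rule there as well, and of the lower ones 9.73%.

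At 30 min, the MAP kinase phosphatase gene dusp5 was 1201-fold higher (215 to 47490; 832 against 1 UMIs; unnamed 8.02-fold), fosl1a 501-fold (214 to 1545), il11b, a cytokine of the interleukin-6 family, 234-fold (100 to 724) and cxcl8a, a neutrophil chemokine, at least 53.4-fold. Among enzymes, pnp5a, a purine nucleoside phosphorylase, was 138-fold higher, sat1a.2, a spermidine acetyltransferase, 44.5-fold (38.5 to 51.7), and odc1, ornithine decarboxylase, 38.5-fold. The oxidase organizer gene noxo1a was 84.4-fold higher, igfbp1a, an insulin-like growth factor binding protein, 82.2-fold (47.8 to 155), atf3 42.5-fold (32.3 to 56.9; unnamed 72.0-fold) and hbegfa, an EGF receptor ligand, 12.5-fold (9.86 to 16.04; unnamed 2.02-fold). By list, pfkfb3, a regulator of glycolysis, was 35.1-fold higher (11.6 to 174; 73 against 3 UMIs), mych 12.1-fold, and pim3 10.8-fold. The hyaluronan receptor gene cd44a was 8.56-fold higher, and cycsb, a cytochrome c, 7.94-fold (7.33 to 8.62). Smaller ratios were those of trib3 (6.88-fold), nuak2 (6.07-fold), rdh10b (4.499-fold), dnajb9b (4.33-fold) and atp2b1a (2.75-fold).

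Neuromast transcription factors were lower at 30 min. The LIM homeodomain gene isl1 was 16.2-fold lower (12.6 to 21.3; unnamed 3.81-fold), gata2a 25.4-fold (12.2 to 63.9), gata2b 21.2-fold, sox3 22.4-fold (18.3 to 27.6; unnamed 2.196-fold) and stox1 27.3-fold. The ligand gene wnt11 was 42.6-fold lower (20.5 to 106), ypel3 44.0-fold (20.03 to 121) and tpst1l, a tyrosylprotein sulfotransferase, 74.8-fold (13.2 to 2983; 1 against 108 UMIs). Lower by list were spry2, a feedback inhibitor of FGF signalling, 12.6-fold, wnt2 8.54-fold (7.00 to 10.5), cdc20 8.83-fold, smad6a 6.58-fold, sesn1 5.35-fold and tfam 4.504-fold. Of 32 neuromast transcription factors, 16 were lower and 2 higher, with a median of −1.27, or −0.95 relative to all genes at −0.32 (unnamed −0.46). The Notch list had a median of −0.87 (0 higher and 9 lower of 27; unnamed −0.41), G2 and M phase −0.85 (0 and 8 of 44; unnamed 0.03), immediate early genes 2.66 (20 and 1 of 30; unnamed 2.37) and inflammation 2.07 (15 and 0 of 28; unnamed 1.45). In all, 863 genes met the rule as higher and 1655 as lower of 7982. Higher genes were 34.3% of those that met it, against 53.7% with TMM and 54.8% with median-of-ratios scaling. Of the 541 higher genes measured in unnamed cells, 55.8% met the rule there, and of the lower ones 11.2%.

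At 1 h, many genes of the first times were still higher, at smaller ratios: fosl1a was 111-fold higher (47.5 to 343), il11b 73.3-fold, sat1a.2 29.6-fold and dusp5 592-fold (106 to 23420; unnamed 3.35-fold). The CART peptide gene cart3 was 130-fold (50.5 to 477; unnamed 2.53-fold) and the relaxin gene rln3a 72.1-fold higher (27.9 to 266). The zinc finger gene sall1b was 148-fold (26.3 to 5868; 216 against 1 UMIs), fosl1b 131-fold (23.2 to 5192; 191 against 1 UMIs), the NADPH oxidase gene nox1 40.8-fold, lima1a 28.2-fold, gadd45ga 18.6-fold (unnamed 4.70-fold), s100a10b 5.16-fold and hk2, hexokinase, 4.83-fold higher. Lower were tppp3, a tubulin-binding protein gene, 30.1-fold (21.4 to 43.8; unnamed 1.37-fold), the repressor gene bcl6a at least 26.3-fold, ccl20a.3 29.8-fold, wnt11 26.2-fold, gsta.2 27.4-fold and pcmtd1 29.4-fold. The angiogenic factor gene vegfab was 94.9-fold lower (16.5 to 3807; 1 against 65 UMIs) and mfsd4aa 89.1-fold (15.4 to 3576; 1 against 61 UMIs). Lower too were the Notch targets hey2, 8.53-fold, and her4.2, 8.09-fold (unnamed 17.4-fold), and the progenitor gene hes6, 7.47-fold. Lower by list were also prc1a 14.3-fold, fkbp4 6.34-fold, ctbp2a 5.01-fold, nqo1 4.86-fold, bmp2a 4.44-fold, unga 4.25-fold, fen1 3.82-fold, raraa 3.79-fold and triobpa 2.49-fold.

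By list at 1 h, the Wnt median was −1.32 (0 higher and 11 lower of 21; unnamed −1.02), the Notch median −1.26 (2 and 12 of 27; unnamed −1.07), G2 and M phase −1.11 (0 and 16 of 47; unnamed −0.996) and S phase −0.85 (0 and 16 of 53; unnamed −1.42), beside −0.34 for all genes. Immediate early genes stood at 0.89 (10 and 2 of 26; unnamed 0.68), inflammation at 1.27 (14 and 1 of 28; unnamed 1.13) and ribosome biogenesis at 0.67, or 1.01 relative to all genes (18 and 0 of 70; unnamed 0.55). Hair cell synapse genes had a median of −0.94 (2 and 2 of 10; unnamed −1.47), at percentile 12.49 of random lists, which rests on few members. In all, 966 genes were higher and 1966 lower by the rule of 8792, and of the 1261 lower genes measured in unnamed cells 41.0% were lower there by the rule, as were 39.6% of the higher ones higher. Higher genes were 32.9% of those that met it, against 56.5% with TMM and 56.4% with median-of-ratios scaling.

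At 3 h, genes of ribosome biogenesis were higher almost throughout: 66 of 70 met the rule as higher and 0 as lower, with a median of 2.203, or 2.001 relative to all genes at 0.20 (unnamed 0.93). The nucleolar genes mybbp1a, npm1a, rrp9 and pes were 7.82-fold (5.98 to 10.4), 7.45-fold (6.83 to 8.12), 7.40-fold and 7.17-fold higher, against 2.03, 2.201, 1.88 and 3.28-fold in unnamed cells. The thioredoxin gene txn was 15.5-fold higher (14.6 to 16.5; unnamed 6.93-fold) and hmox1a, heme oxygenase, 8.70-fold (unnamed 1.97-fold). Other higher genes were odc1 at 26.2-fold, gadd45ga at 17.6-fold (14.1 to 22.1; unnamed 3.22-fold), mdkb, a midkine gene, at 17.6-fold (unnamed 2.03-fold), rln3a at 134-fold (51.7 to 493) and cart3 at 101-fold (39.0 to 374). Heat shock genes had a median of 1.38 (11 higher and 0 lower of 21; unnamed 0.86), with hsp70.2 at 24.7-fold (12.2 to 58.6; unnamed 40.6-fold), hsp70.1 at 13.6-fold and hsp70.3 at 9.04-fold. Higher by list were also cldni 8.06-fold, lhfpl5b 7.58-fold, timm10 6.65-fold, anxa2a 5.85-fold, rbp4 5.75-fold, gapdh 4.16-fold, hspa9 3.82-fold, aldocb 3.71-fold and ankrd1a 3.66-fold. Of these, cldni, lhfpl5b, rbp4, gapdh and aldocb were 8.50, 6.01, 7.39, 4.58 and 7.15-fold higher in unnamed cells. The genes anxa2a and ankrd1a are also leading genes of unnamed cluster 2, which had 1100 cells at 3 h against 412 at homeostasis. Likewise, rbp4 is a leading gene of mesenchyme cluster 15.

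Lower at 3 h were prox1a, a homeodomain gene, 22.4-fold (10.7 to 56.4; unnamed 2.72-fold), the Notch ligand gene jag2a 13.5-fold (unnamed 12.2-fold), the Wnt antagonist gene dkk2 10.7-fold, fgf10b 47.3-fold (8.24 to 1892; 1 against 78 UMIs), dhrs3a 7.66-fold, fzd8a 7.00-fold and slc7a11, a cystine transporter, 6.77-fold. The Notch list had a median of −1.31, or −1.51 relative to all genes (1 higher and 12 lower of 27; unnamed −0.50), FGF −0.73 (3 and 5 of 20; unnamed −0.10) and endoplasmic reticulum stress −0.56 (0 and 6 of 23; unnamed 0.31). Progenitor genes had 1.38 (7 and 0 of 16; unnamed −0.12) and oxidative stress 0.50 (5 and 5 of 23; unnamed 0.27). Medians at least as high in unnamed cells included those of G2 and M phase at 0.56 (4 and 0 of 48; unnamed 0.59), mitochondrial genes at 0.56 (11 and 0 of 35; unnamed 0.77) and glycolysis at 0.42 (6 and 1 of 25; unnamed 0.78), the last at percentile 83.67. Among others were immediate early genes at 0.38 (6 and 0 of 26; unnamed 0.88, leukocytes 1.907), G1 cyclins at 0.34 (5 and 1 of 18; unnamed 0.75) and S phase at 0.13 (1 and 2 of 52; unnamed 0.50). In all, 1219 genes were higher and 613 lower by the rule of 8167, with 66.5% of those that met it higher, against 48.6% with TMM and 50.7% with median-of-ratios scaling. Of the 1046 higher genes measured in unnamed cells, 32.9% met the rule there, and of the lower ones 16.98%. Among genes that the rule named at 3 h, some had most of their UMIs in 1 cell. The photoreceptor genes gngt2b, opn1lw2, rbp4l, opn1sw1 and gnb3b, at least 272, 145, 102, 101 and 44.0-fold higher, had 299 of 495, 252 of 264, 141 of 186, 170 of 184 and 54 of 80 UMIs in 1 cell. Smaller parts in 1 cell, yet above 10%, were 46 of 245 UMIs of cart3 at 3 h and 18 of 79 at 5 h. So were 13 of 111 of cxcl8a at 30 min and, at homeostasis, 48 of 326 of ccl20a.3 and 38 of 369 of fosab. Under the name sat1a.2, 1 ID was at least 91.8-fold higher, with UMIs at 3 h alone, and another at least 38.2-fold lower, with 0 UMIs at 3 h alone. Summed under the name, the log2 ratio was 0.54, so both values reflect which ID holds the UMIs in this file and not a difference of the gene. The file of this library lists fewer genes than the others. The genes tapbp.1 (at least 45.1-fold), fndc7a (37.7-fold), gal3st1a (at least 35.6-fold), slc16a12b (at least 18.6-fold), sptbn1 (76.4-fold, 13.5 to 3042, 1 against 126 UMIs), pcp4b (at least 14.8-fold) and ucp3 (12.4-fold) were lower too. Matched by symbol, the ratio of ucp3 was larger still and the rest stayed within their intervals, and whether annotation sets them stays open. In all, 31 genes lay at least 5 times below every other library at 3 h.

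At 5 h, ribosome biogenesis genes were again higher, with 57 of 70 meeting the rule as higher and 0 as lower and a median of 1.53, while the median in unnamed cells was −0.01. Named genes of this kind were knop1, a nucleolar protein gene, 9.18-fold higher (7.86 to 10.8; unnamed 3.60-fold), and abcf1, of an ABC family that acts in translation, 6.505-fold (5.62 to 7.55; unnamed 2.64-fold). Also higher were cad, the enzyme that starts pyrimidine synthesis, 6.32-fold (unnamed 1.74-fold), dus2 9.75-fold, timm10 5.40-fold, sox4a 5.43-fold (unnamed 1.28-fold), gadd45ga 9.02-fold (7.17 to 11.4; unnamed 1.45-fold), cart3 34.3-fold (12.9 to 129) and the cystatin gene cst14b.2 15.7-fold. The digestive enzyme genes ctrl, c6ast4 and try were 17.9, 19.7 and 10.3-fold higher here and 7.43, 4.81 and 6.82-fold higher in unnamed cells. Lower were rrm2, of ribonucleotide reductase, 20.2-fold (9.15 to 55.8; unnamed 5.94-fold), ccl20a.3 93.9-fold (25.8 to 778; 2 against 326 UMIs), gsta.2 68.3-fold (23.2 to 333; 3 against 356 UMIs) and cyth4b 21.3-fold (7.10 to 105; 3 against 111 UMIs). So were ms4a17a.10 10.4-fold, rcn3 10.23-fold, lpin1 9.85-fold and ms4a17a.1 8.84-fold. By list, pdia3, a protein folding enzyme gene, was 4.21-fold lower (3.99 to 4.45; unnamed 1.74-fold), nusap1 6.91-fold, ccnb3 5.85-fold and id2b 5.63-fold.

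The medians at 5 h were −1.07 for G2 and M phase (0 higher and 10 lower of 44; unnamed −0.46), −0.93 for inflammation (0 and 6 of 20; unnamed −0.31), −0.81 for endoplasmic reticulum stress (1 and 6 of 23; unnamed −0.13), beside 0.08 for all genes. They were 0.85 for G1 cyclins and growth regulators (4 and 1 of 19; unnamed −0.03), −0.46 for epithelial structure (1 and 6 of 31; unnamed −0.18), 0.49 for mitochondrial genes (4 and 0 of 36; unnamed 0.03), 0.43 for progenitor genes (6 and 1 of 13; unnamed 0.05, percentile 92.35) and −0.41 for immediate early genes (0 and 5 of 24; unnamed −0.39). In all, 731 genes were higher and 593 lower by the rule of 8006. Higher genes were 55.2% of those that met it, against 47.4% with TMM and 46.9% with median-of-ratios scaling, so which direction held more genes depends on the scaling. Of the higher genes measured in unnamed cells, 9.32% met the rule there, and of the lower ones 22.8%.

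**Figure D2:**
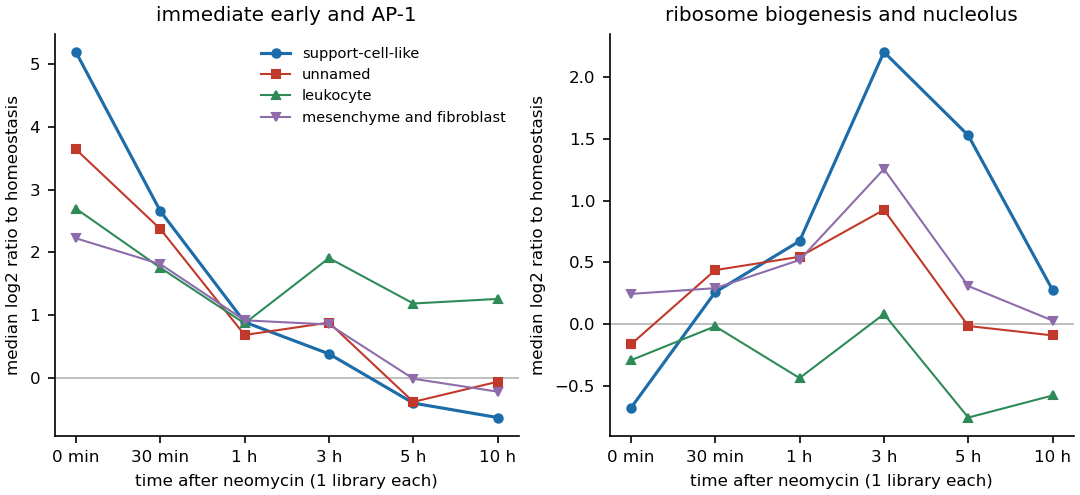
Median log2 ratio to homeostasis (y axis) of the immediate early and the ribosome biogenesis list at the 6 times (x axis) in support-cell-like cells, unnamed cells, leukocytes and mesenchyme. Immediate early genes are above 0 in each class at 0 min (5.198, 3.64 and 2.70 in the first 3), while ribosome biogenesis at 5 h is at 1.53 in support-cell-like and −0.01 in unnamed cells.

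At 10 h, the histone H4 genes under the name hist1h4l were 31.8-fold and 21.4-fold higher, against 52.4 and 7.49-fold in unnamed cells. The chemokine gene ccl38.6 was 168-fold higher (46.1 to 1393; 297 against 2 UMIs), ccl34b.1 10.1-fold, map2k4a, a MAP kinase kinase gene, 72.4-fold (12.5 to 2903; 64 against 1 UMIs), dock1 20.1-fold (unnamed 26.2-fold) and ttc39a 13.1-fold. Of these, ccl34b.1 is also a leading gene of the leukocyte cluster, 16. Its UMIs were in 13.3% of support-cell-like and 7.79% of unnamed cells at 10 h. Also higher were ngfa, of the nerve growth factor family, 10.96-fold (unnamed 9.57-fold) and fat1b, an atypical cadherin gene, 8.93-fold (unnamed 3.58-fold). Insulin RNA (ins) was at least 119-fold higher, with 266 of 315 UMIs in 1 cell. Lower were bhlhe40, a repressor of the circadian clock, 22.2-fold (13.3 to 40.1; unnamed 2.23-fold), cry1ab 16.6-fold, gadd45aa 17.7-fold (8.36 to 44.8; unnamed 1.25-fold higher) and ccl20a.3 16.96-fold. So were gsta.2 10.5-fold, fosab 10-fold (unnamed 6.68-fold), ms4a17a.2 9.55-fold, ms4a17a.10 8.41-fold and tmsb1, a thymosin beta gene, 7.35-fold (6.86 to 7.89; unnamed 1.14-fold). By list, pola1, of DNA polymerase alpha, was 5.94-fold higher (unnamed 1.66-fold), tead1b 3.97-fold and vgll4a 3.39-fold (unnamed 6.24-fold).

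At 10 h all genes had a median of 0.26. Progenitor genes had a median of 1.58 (7 higher and 1 lower of 16; unnamed −0.45), S phase 0.79 (12 and 1 of 55; unnamed −0.19), Wnt 0.76 (6 and 0 of 25; unnamed 0.10), Notch 0.73 (10 and 1 of 27; unnamed 0.56), FGF 0.66 (5 and 2 of 19; unnamed 0.21), Hippo-YAP 0.60 (3 and 0 of 13; unnamed 0.56, percentile 82.95) and synapse genes 0.53 (1 and 1 of 10, at percentile 65.49 of random lists of like expression). Relative to all genes these were 1.32, 0.53, 0.50, 0.47, 0.40, 0.34 and 0.27. Immediate early genes had −0.64 (2 and 5 of 23; unnamed −0.07), glycolysis −0.61 (2 and 4 of 25; unnamed −0.36), inflammation −0.59 (1 and 3 of 21; unnamed 0.34) and endoplasmic reticulum stress −0.55 (2 and 8 of 23; unnamed −0.09). In all, 1553 genes were higher and 482 lower by the rule of 9135. Higher genes were 76.3% of those that met it, against 50.03% with TMM and 45.9% with median-of-ratios scaling, so the excess of higher genes at 10 h depends on the scaling. Of the 326 higher genes measured in unnamed cells, 45.1% met the rule there, and of the lower ones 9.87%. Mitochondrially encoded genes held 1.47, 2.26, 2.23, 2.16, 1.66, 2.05 and 2.65% of the UMIs of support-cell-like cells from homeostasis to 10 h, and 1.51% at 10 h against 1.39% at homeostasis in unnamed cells. The share was thus highest at 10 h, and RNA quality was not tested.

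**Figure D3:**
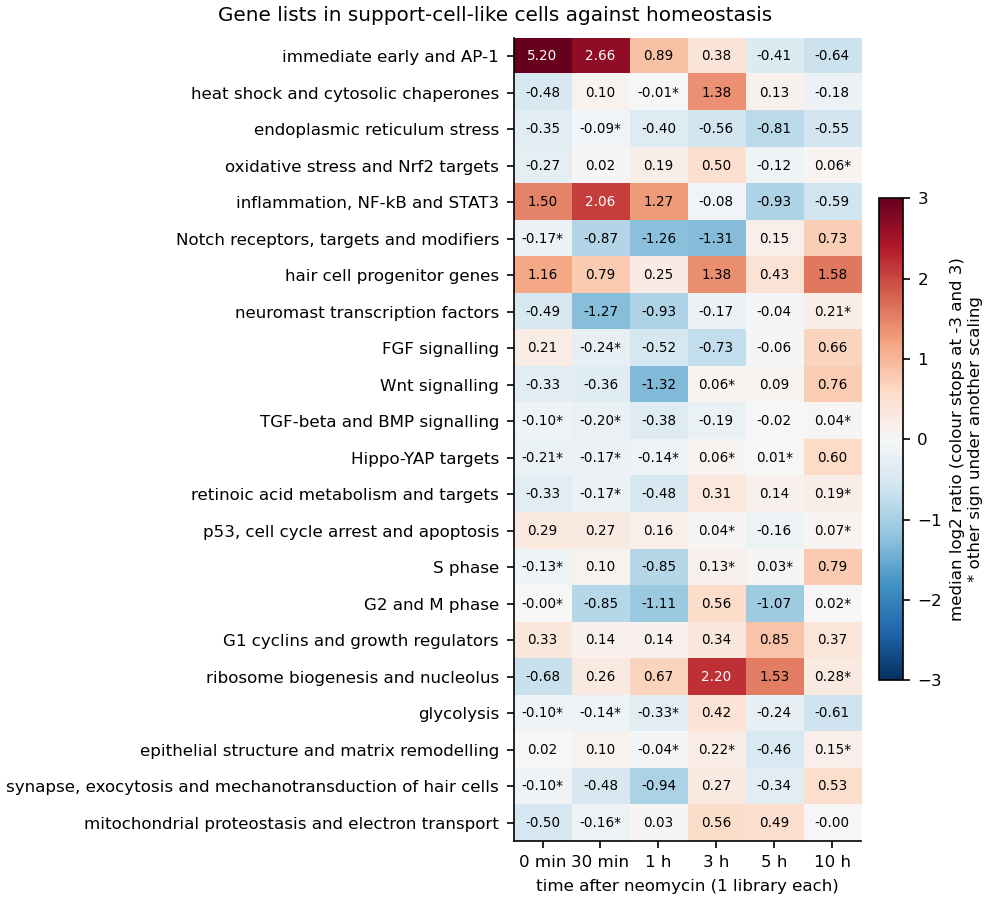
Median log2 ratio to homeostasis in support-cell-like cells for the 22 gene lists (y axis) at the 6 times after neomycin (x axis), with a star where another scaling gives the other sign. The largest value is 5.198 for immediate early genes at 0 min, and 33 of the 132 medians carry a star, none of them beyond 0.33 in size.

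Smaller list medians, by time from 0 min to 10 h, were −0.33, −0.17, −0.48, 0.31, 0.14 and 0.19 for retinoic acid, with the sign turning under a scaling at 30 min and 10 h. They were −0.10, −0.20, −0.38, −0.19, −0.02 and 0.04 for TGF-beta and BMP, where the 0 min, 30 min and 10 h signs turn, and 0.29, 0.27, 0.16, 0.04, −0.16 and 0.07 for p53 and apoptosis genes, where those at 3 h and 10 h turn. The p53 list stood above 99.43% of matched random lists at 0 min, with 5 higher and 2 lower of 27, but its median was 0.27 in unnamed cells and 0.68 in leukocytes as well. The immediate early list lay above all random lists at 0 min, as did heat shock at 3 h, while Notch at 10 h lay above 99.9% of them and endoplasmic reticulum stress at 5 h below nearly all.

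The 9 genes of interest took different courses. The neural factor gene sox4a (ENSDARG00000004588) had 34.5 CPM at homeostasis and 51.3, 224, 287, 254, 187 and 93.8 CPM from 0 min to 10 h, higher by the rule from 30 min on, at up to 8.31-fold, and it stayed at 15.4 to 33.1 CPM in unnamed cells. The gene of the hair cell master regulator, atoh1a (ENSDARG00000055294), had 99.2 CPM and then 196, 126, 43.8, 295, 338 and 133 CPM, 2.27-fold lower at 1 h and 2.97 and 3.41-fold higher at 3 h and 5 h. The Notch target her4.1 (ENSDARG00000056732) was at 148 CPM and then 73.8, 62.9, 44.6, 46.2, 304 and 180 CPM, lower by the rule until 3 h (3.32-fold at 1 h) and 2.05-fold higher at 5 h. The homeodomain gene isl1 (ENSDARG00000004023) went from 224 CPM to 28.4, 13.8, 51.0, 161, 195 and 281 CPM.

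The ligand genes fgf10a (ENSDARG00000030932) and fgf3 (ENSDARG00000101540) were both low early. With 57.01 CPM at homeostasis, fgf10a had 21.8, 4.89, 4.75, 55.4, 54.6 and 56.3 CPM, and fgf3 had 16.3 CPM and then 1.32, 1.56, 1.79, 5.34, 14.99 and 33.98 CPM, 12.4-fold lower at 0 min and 2.08-fold higher at 10 h. The peroxiredoxin gene prdx1 (ENSDARG00000058734) had 29.7 CPM and then 29.5, 41.1, 52.96, 60.5, 77.9 and 67.1 CPM, 2.62-fold higher at 5 h. The forkhead gene foxg1a (ENSDARG00000070769) was 2.37-fold (1.66 to 3.45) and 4.01-fold (2.59 to 6.47) lower at 0 min and 30 min, from 21.4 CPM. The Notch ligand gene dld (ENSDARG00000020219) was low throughout, at 5.39 CPM and then 14.8, 9.34, 5.91, 14.7, 13.1 and 23.0 CPM, and its higher values at 0 min and 3 h turned to lower ones under other clusterings.

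**Figure D4:**
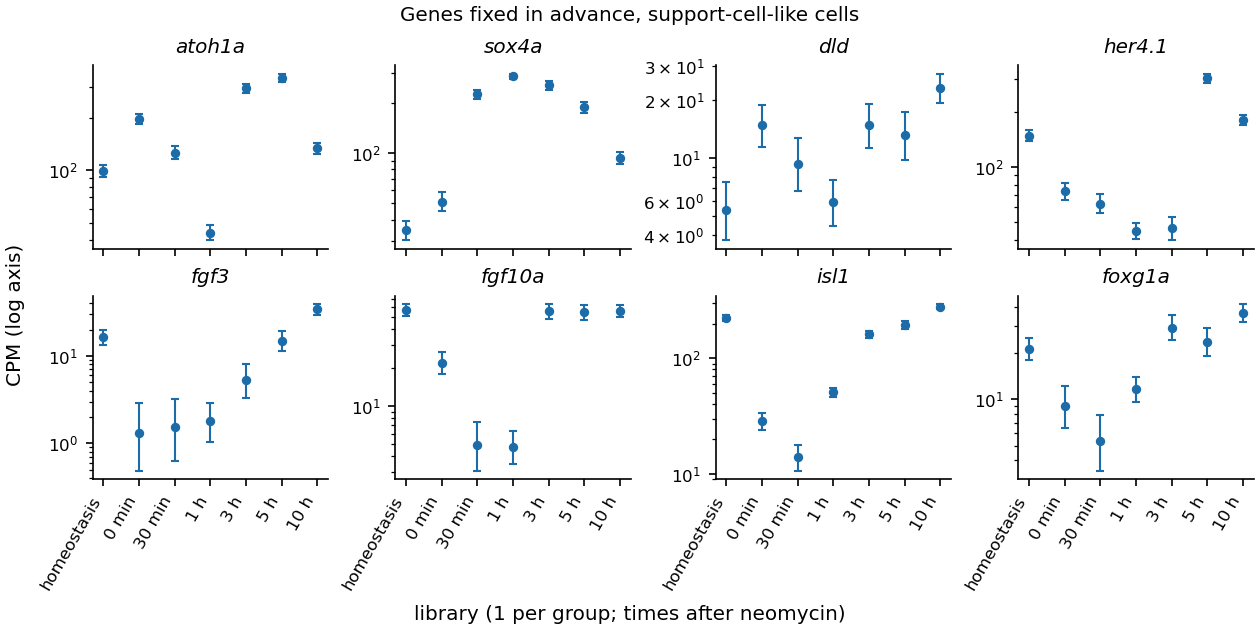
CPM on a log axis (y) of atoh1a, sox4a, dld, her4.1, fgf3, fgf10a, isl1 and foxg1a in support-cell-like cells of the 7 libraries (x), with exact 95% Poisson intervals. The lowest point of isl1 is 13.8 CPM at 30 min, and the highest of sox4a is 287 CPM at 1 h.

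Subsets of the class differed for some genes. The thioredoxin gene txn was 41.2-fold higher in central-like and 2.56-fold in mantle-like cells at 3 h, a ratio of ratios of 16.1 (13.7 to 19.0), and 24.2 against 1.38-fold at 5 h, 17.6 (14.8 to 20.9). Mantle-like cells held 1012 CPM of txn already at homeostasis, against 65.4 CPM in central-like cells. At 30 min, gadd45ga was 42.7-fold higher in central-like and 3.88-fold in mantle-like cells, and hbegfa 25.4-fold in central-like and 5.89-fold in polar-like cells. On the lower side at 30 min, wnt2 was 45.8-fold lower in mantle-like and 8.60-fold in central-like cells, fgf10a 36.3-fold in polar-like and 5.55-fold in central-like cells, and gata2b 31.4-fold in central-like and 3.72-fold in polar-like cells. The LIM gene isl1, a central support cell marker used in naming, stood at 1 h at 0.224 of its homeostasis level in central-like cells but at 1.59 in polar-like cells. Polar-like cells were mostly cluster 1 at 1 h (2238 of 2325) and cluster 12 at homeostasis (838 of 904), with central marker scores of 0.031 and −0.843. The isl1 values may therefore follow from the naming. Of 509 such comparisons, 31 had a ratio of ratios whose bound lay beyond 2-fold. Polar-like cells were under 2% of the 0 min and 3 h libraries, where single clusters held most support-cell-like cells, so the subsets are less well separated there. At the other times too, the central-like name went mostly to other clusters than at homeostasis, as did the polar-like name at 30 min and 1 h. Ratios within these subsets therefore also compare clusters.

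Against the 0 min library, which shared the treatment, 449 genes were higher and 443 lower at 30 min, 803 and 1086 at 1 h, 2077 and 940 at 3 h, 1550 and 853 at 5 h, and 1853 and 694 at 10 h. Higher genes were 50.3% of those that met the rule at 30 min, 42.5% at 1 h, 68.8% at 3 h, 64.5% at 5 h and 72.8% at 10 h, and with TMM it was 56.9, 52.9, 46.0, 46.2 and 38.6%. With median-of-ratios scaling it was 63.1, 57.2, 50.8, 49.1 and 39.3%. Immediate early genes were already lower at 30 min than at 0 min, at a median of −1.52.

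Over the 7 libraries, 24 genes were at their highest at homeostasis by the rule against every other library, 94 at 0 min, 38 at 30 min, 26 at 1 h, 137 at 3 h, 0 at 5 h and 316 at 10 h. The counts at 1 h, 3 h, 5 h and 10 h depend on the scaling, as they were 45, 72, 1 and 169 with TMM and 45, 78, 1 and 156 with median-of-ratios scaling, which also gave 39 at homeostasis. Without doublet removal 18 genes were highest at 5 h. At homeostasis these included mhc1uba, a class I histocompatibility gene, 5.97-fold (3.04 to 12.8) above the next library, sult1st7 3.15-fold, rcn3 3.01-fold, mid1ip1l 2.61-fold and degs1 2.37-fold. At 0 min they included egr2a 59.3-fold (38.2 to 97.4), dusp2 40.9-fold, fosab 31.4-fold (29.3 to 33.8), jdp2b 17.3-fold and nr4a1 15.17-fold. The 30 min genes were plek2 3.64-fold, fabp11a 3.401-fold, zfand5a 3.26-fold, il11b 3.2-fold and il4r.1 2.81-fold, and those of 1 h were tac3b 4.001-fold, iqsec1b 3.53-fold, npas2 3.32-fold, bcar1 3.25-fold and nox1 2.84-fold. At 10 h, hist1h4l was 20.1-fold and 12.9-fold above the next library for its 2 IDs, the yippee-like gene ypel1 15.08-fold and rn7sk, a small nuclear RNA, 6.68-fold, beside ins. At 10 h rn7sk was higher in other classes too, at 36.2 against 8.45 CPM at homeostasis in unnamed cells, 53.4 against 5.01 in leukocytes and 61.1 against 10.5 in mesenchyme. The 5 named at 3 h were sat1a.2, rbp4l, opn1sw1 and opn1lw2, described above, and ckmt2a, with 40 of its 67 UMIs in 1 cell.

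Hair-cell-like cells could be compared at 0 min, 30 min and 3 h, with 86, 98 and 85 cells against 173 at homeostasis. They held more fosab RNA at all of these times, 194-fold (115 to 355), 153-fold (90.8 to 280) and 116-fold (69.0 to 213), from 21.0 CPM to 4062, 3205 and 2436 CPM. In support-cell-like cells the ratios were 111, 3.08 and 3.53-fold. Also higher were junba, at 209-fold at 0 min (36.7 to 8316; 108 against 1 UMIs), egr4, at 100-fold (33.8 to 491) at 30 min and 98.8-fold (33.3 to 483) at 3 h (3 UMIs at homeostasis), cebpb, at 122-fold (21.1 to 4882) at 0 min and 226-fold (39.9 to 9001) at 30 min (1 UMI at homeostasis), and atf3, with 156 UMIs against 0 at 30 min. The RNA-binding protein gene lin28a had 226 UMIs at 30 min and 125 at 3 h against 0. Lower were hsp90aa1.2 3.05-fold, dap1b 3.52-fold, tspan3a 3.47-fold, apoa2 3.08-fold and h3f3d 2.24-fold at 0 min. At 30 min the homeodomain gene barhl1a was 6.24-fold lower (3.53 to 12), nkx3.2 2.45-fold and ctdsp2 4.17-fold, and at 3 h spag8 was 8.33-fold and atp6v1c2 7.46-fold lower. Lower at 3 h by more were fndc7a, 53.6-fold (9.34 to 2142; 1 against 79 UMIs), and ucp3, 10.3-fold (6.21 to 18.3). Both were lower in support-cell-like cells of this library too, where annotation was left open. The sat1a.2 ID with UMIs at 3 h alone had 74 UMIs against 0 here. By the rule, 86 genes were higher and 30 lower at 0 min, 114 and 24 at 30 min, and 236 and 41 at 3 h. The 1 h, 5 h and 10 h libraries had under 50 of these cells.

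The share of support-cell-like cells with at least 2 UMIs of G2 and M phase genes, at 1000 UMIs per cell, was 41.4, 31.3, 34.5, 28.2, 56.5, 44.3 and 41.5% from homeostasis to 10 h, after leaving out 0, 1116, 1222, 1961, 0, 355 and 755 shallower cells. Hair-cell-like cells, which do not divide, gave 39.9, 42.5, 59.8, 59.09, 52.9, 34.6 and 50% at median depths of 3795, 4111, 4096.5, 3854, 5317, 4051.5 and 5775 UMIs. Most of these shares are thus at background and are not read as cycling. Without thinning they were 69.4, 43.0, 43.8, 40.1, 94.3, 67.0 and 59.0%. Without hmgb2a and hmgb2b, chromatin genes abundant in all classes, 3.88, 3.87, 3.62, 2.23, 6.20, 2.40 and 4.85% of support-cell-like cells had 2 such UMIs, against 1.73, 0, 0, 4.55, 0, 0 and 16.7% of the few hair-cell-like cells. With the S phase list, left without stmn1a, the shares were 10.5, 10.9, 15.8, 8.63, 17.4, 14.7 and 22.5%, against 6.36, 3.75, 5.75, 6.82, 7.06, 0 and 0% in hair-cell-like cells, and 20.1, 14.2, 19.5, 13.6, 48.5, 30.3 and 36.7% without thinning. Thinned unnamed cells gave 12.9, 8.27, 8.70, 5.08, 25.4, 12.7 and 14.4% with this S phase list. Their share was thus the larger at homeostasis and at 3 h, so the higher 3 h value was not particular to support-cell-like cells.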

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

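The tests in this part were chosen after the results they bear on had been seen, except the first test of free RNA and the 2 other scalings, which were planned. Immediate early genes were higher at 0 min, and not in support-cell-like cells alone. The list median was 3.644 in unnamed cells (1.69 to 5.42) beside 5.198 in support-cell-like cells, and 1.127 to 2.536 within each of 4 unnamed clusters with at least 50 cells in both libraries (1 of these intervals held 0). Cluster 11, the largest unnamed cluster at 0 min, is not among them, with 1082 cells there against 7 at homeostasis. The pooled 3.644, higher than in each of the 4, therefore also compares different clusters. Free RNA of support cells in every droplet would carry the gains of its genes in 1 ratio. Among 21 abundant members, the ratio of unnamed to support-cell-like levels at 0 min spanned 30.14-fold, from 3.41% for nr4a1 to 103% for junbb. These are levels and not gains, so RNA that unnamed cells held already at homeostasis could widen the span. It therefore cannot decide how much of the rise in unnamed cells was free RNA. A first test, written before its result, set the gain of 28 immediate early genes in unnamed cells (20.6% of that in support-cell-like cells, 12.3 to 45.9) against 10 support markers (8.88%, 2.80 to 17.7). Its intervals overlapped, so it decided nothing by that comparison, and the second was chosen after it. The median gain, 12.3 to 45.9%, did lie above the limit from nr4a1. At 1 ratio, free RNA of support cells was thus not the whole of this median gain. Sorting was common to all libraries, but handling of the treated larvae alone and neomycin itself cannot be told apart, because leukocytes had a median of 2.698 and no library came from mock-treated larvae, so a response of several cell types to neomycin stays a hypothesis.

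The hair-cell-like share was as high at 3 h as at homeostasis and lower at the other times. The lowest depth kept in each file could account for the gap at 0 min and 30 min, where the lower of both shares was 6.857% above 1700 UMIs against 6.96% at homeostasis, but not for that at 1 h, 5 h and 10 h, whose highest upper bound was 3.587% against a lower bound of 4.92% at 3 h. A homeostasis library under the 3 h label is excluded: of 437 genes at least 2-fold higher at both 1 h and 5 h than at 0 min, 289 (66.13%) met the size rule as higher at 3 h than at homeostasis and 3 as lower. That test replaced an earlier one (1832 genes met the rule, against at most 4 between random parts of the homeostasis cells), since 2 homeostasis libraries of different days might also differ by more than parts of 1. Hair-cell-like cells at 3 h held 116.2-fold more fosab RNA (69.0 to 213) than at homeostasis, against 3.53-fold in support-cell-like cells, which goes with cells that lived through the treatment, but leukocytes also had an immediate early median of 1.907 at 3 h, and handling and new hair cells stay open.

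Ribosome biogenesis genes were higher at 3 h and 5 h. A factor acting equally on all cells of a library is excluded as the whole cause, although part of the 3 h value was shared. The list median in unnamed cells was 0.9262 at 3 h (0.848 to 1.06, against 2.04 to 2.36 in support-cell-like cells) and −0.01393 at 5 h (−0.12 to 0.09, against 1.32 to 1.64). These intervals show the spread between the genes of the list. Within each of 4 unnamed clusters, which differ in share between libraries, the list median was 0.6461 to 1.498 at 3 h and −0.2027 to 0.2336 at 5 h. Scaling is excluded as well, as the lowest median at both times was 1.443 under the other scalings. In central-like cells alone the lower median was 1.802. That cannot exclude the shares of subsets, since different clusters carried the central-like name at homeostasis, 3 h and 5 h. Growth of support cells after hair cell loss is an open hypothesis that was not tested.

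Other results were listed because 2 times went opposite ways against homeostasis. These differences were not tested, as each time is 1 library. By log2 ratio, atoh1a was at 1.77 at 5 h and −1.18 at 1 h, her4.1 at 1.04 at 5 h and −1.73 at 1 h, and fgf3 at 1.06 at 10 h and −3.63 at 0 min. Among list medians, immediate early genes were at 5.2 at 0 min and −0.64 at 10 h, inflammation at 2.07 at 30 min and −0.93 at 5 h, Notch at 0.73 at 10 h and −1.31 at 3 h, FGF at 0.66 at 10 h and −0.73 at 3 h, and Wnt at 0.76 at 10 h and −1.32 at 1 h. S phase was at 0.79 at 10 h and −0.85 at 1 h, G2 and M phase at 0.56 at 3 h and −1.11 at 1 h, ribosome biogenesis at 2.2 at 3 h and −0.68 at 0 min, and hair cell synapse genes at 0.53 at 10 h and −0.94 at 1 h, which says little, as 1 higher and 1 lower of 10 members met the size rule at 10 h and 2 and 2 of 10 at 1 h. A condition that each such median keep its sign under every scaling was added after the list had been seen and removed nothing. Outside the main measurement, 0.966% of the UMIs at 10 h lay on gene IDs that not all files share, and 59 barcodes were set apart for their erythroid UMIs.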

How the results depend on the processing

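Tests and alternatives chosen after the data had been seen are the minimum of 1700 UMIs, the clustering without the added steps, the list without hmgb2a and hmgb2b, central-like cells alone, genes beyond the unnamed cells, values without each gene's highest cell and the choice of 16 genes per direction. Of 1949 list medians recomputed, 1828 kept their value within the limits set, 119 moved and 2 took the other sign, and of 2992 values of named genes 2581 kept it, 395 moved and 16 took the other sign. Of 277 gene counts 226 stayed within 1.5 times, of 33 hair-cell-like shares 22 stayed within the interval, and of 49 shares outside the neuromast classes 31 did. No paired analysis was possible because each group is 1 library. At resolution 0.5 and without the added steps no cluster was hair-cell-like, and in 1 h and 10 h clustered on their own none was either, so these gave no hair-cell-like value. The size rule asks for 2-fold and so leaves out differences of 1.5-fold by its design. It recovered 86 to 96% of simulated differences of 3- to 10-fold at every time, in counts without variation between libraries. Where no cause is named, the cause was not tested.

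Direction turned for 18 values, as log2 ratios to homeostasis. The dld ratio at 0 min was −0.58 without doublet removal, −0.16 at resolution 0.5, −0.21 at resolution 2.0 and −0.50 without the added steps, and at 3 h it was −0.19, −0.0918 and −0.0276 for the first 3 of these. Matched by symbol, sat1a.2 at 3 h was 0.54, since both IDs are then summed. With 0 min as the reference, the 30 min values were −1.52 for the immediate early list, −0.61 for fosl1a, −0.63 for igfbp1a, −0.76 for noxo1a and −0.0906 for pnp5a. Those at 1 h were −0.21 for the inflammation list, −2.78 for fosl1a, 0.84 for isl1 and −0.14 for sat1a.2, and dld at 5 h was −0.17, since these had already differed from homeostasis at 0 min.

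With at least 1000 UMIs per cell, hair-cell-like shares were 4.62% at 0 min, 5.41% at 30 min and 1.31% at 1 h, the shares outside the neuromast classes 47.0, 46.8, 45.3 and 22.6% at 0 min, 30 min, 1 h and 10 h, and 2 genes were highest at 5 h. With at least 1700 UMIs before clustering, hair-cell-like shares were 7.60, 7.10, 7.75 and 1.995% from homeostasis to 1 h, 2.49% at 5 h and 0.677% at 10 h, and the outside shares 26.7, 46.9 and 45.3% from homeostasis to 30 min, 39.9% at 5 h and 24.0% at 10 h. Cycling shares were then 39.1% at homeostasis and 35.8% at 0 min, 476 genes were higher and 635 lower at 0 min, 614 higher at 1 h, 592 met the rule between 30 min and 0 min, and 13 and 6 were highest at 1 h and 5 h. Fewer cells can lower such counts, but the number of genes highest at 5 h rose from 0 to 6.

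Without doublet removal, the hair-cell-like share was 5.88% at homeostasis, the outside share 41.6% at 1 h, and 18 genes were highest at 5 h. At resolution 0.5 the outside share was 42.7% at 5 h and 18.6% at 10 h, with 1 gene highest at 5 h. At resolution 2.0 it was 41.6% at 5 h, the cycling share at 3 h was 59.8%, and 1 gene was highest at 5 h. With each library clustered on its own, the hair-cell-like share at 30 min was 5.01% and the outside share at 5 h 41.7%. Without the added steps, outside shares were 28.9, 42.0, 41.9 and 41.7% from homeostasis to 1 h, cycling shares 37.5, 29.8 and 60.6% at 30 min, 1 h and 3 h, and 2 genes were highest at 5 h.

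Cycling shares without thinning were 69.4, 43.0, 43.8, 40.1, 94.3, 67.0 and 59.0% from homeostasis to 10 h, since deeper cells hold more UMIs. With at least 3 UMIs of the list they were 20.2, 16.7, 19.4, 13.3, 35.3, 22.1 and 21.5%, and without hmgb2a and hmgb2b 3.88, 3.87, 3.62, 2.23, 6.20, 2.40 and 4.85%.

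With TMM scaling, 626 genes were lower at 0 min, 1057 lower at 30 min, 1533 higher and 1178 lower at 1 h, and 951 higher and 950 lower at 10 h, and 45, 72, 1 and 169 were highest at 1 h, 3 h, 5 h and 10 h. With median-of-ratios scaling, 1031 were lower at 30 min, 1525 higher and 1181 lower at 1 h, and 900 higher and 1060 lower at 10 h, and 39, 45, 78, 1 and 156 were highest at homeostasis, 1 h, 3 h, 5 h and 10 h.

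With a minimum of 200 UMIs, which leaves fewer genes, 463 were higher and 582 lower at 0 min, 522 and 747 at 30 min, 622 and 932 at 1 h, 733 and 359 at 3 h, 426 and 379 at 5 h, and 579 higher at 10 h. Against 0 min, 450, 1006, 1712, 1368 and 1262 met the rule from 30 min to 10 h, 77 and 115 were highest at 3 h and 10 h, and 37, 38 and 71 met it in hair-cell-like cells at 0 min, 30 min and 3 h, where a minimum of 20 UMIs gave 193, 238 and 467 and the main minimum 116, 138 and 277.

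In central-like cells alone, 556 genes were higher and 1055 lower at 30 min, and 2 were highest at 5 h. With 0 min as the reference, 449 were higher and 443 lower at 30 min, 1086 lower at 1 h, 2077 higher and 940 lower at 3 h, and 1550 higher at 5 h. Counted only where the ratio lay beyond that of unnamed cells, 69 were higher and 189 lower at 0 min, 86 and 365 at 30 min, 128 and 170 at 1 h, 218 and 105 at 3 h, 223 and 40 at 5 h, and 31 and 32 at 10 h, where unnamed cells are few. Matched by symbol, 1 gene was highest at 5 h, and with the mean over cells 40 at homeostasis and 1 at 5 h.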

Other observations

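The genes and lists in this part were chosen after their values had been seen, and no test was run on them. Leukocytes were 1.78% of cells (1.43 to 2.19) at homeostasis, 1.14% at 0 min, 2.41% at 30 min, 1.69% at 1 h, 3.94% (3.29 to 4.67) at 3 h, 5.74% (4.99 to 6.56) at 5 h and 3.35% at 10 h. Mesenchyme ran from 2.68% at homeostasis to 5.25% at 5 h and was 3.14% at 10 h. In support-cell-like cells the nuclear receptor gene nr1d2a was at 218 CPM at 0 min against 24.8 at homeostasis, and in unnamed cells at 235 against 29.0. Other genes tied to the circadian clock were nfil3, at 89.0 CPM at 0 min against 10.9, per2, at 50.3 at 30 min against 8.8, npas2, at 39.5 at 1 h against 0.9, and ciarta, at 9.4 at 10 h against 64.6 (unnamed 24.1 against 92.5). The hour of day of each library was not given in the sources used here.

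RNA of other tissues was present in support-cell-like cells at levels that differed between libraries. Pancreas enzyme genes together had 41.9 CPM at homeostasis, 445 at 0 min, 7.8 at 30 min, 129 at 1 h, 81.1 at 3 h, 546 at 5 h and 117 at 10 h, and in unnamed cells 44.3, 306, 9.7, 92.2, 68.8, 428 and 108 CPM. Erythroid genes had 170, 51.7, 87.4, 75.3, 81.8, 354 and 517 CPM in support-cell-like cells. At 3 h, 31 genes lay at least 5 times below and 32 at least 5 times above every other library, and at 10 h 68 lay above.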
